A study of Mus musculus with 2 samples.

How the data were processed

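RNA of medullary thymic epithelial cells sorted by MHC class II level was sequenced in 2 libraries, 1 per group, from pooled mouse thymi. RNA was extracted with Trizol and poly(A)-selected, and libraries were made with a TruSeq kit that does not keep strand, per the labels. Each deposited file holds 1 column of RPKM (reads scaled by transcript length and library depth) per RefSeq transcript line, computed by the authors. The submitters' processing notes name CASAVA, Bowtie 1.0.0, bedtools and mouse build mm9, without stating the role of each, and how reads shared by isoforms or paralogs were treated is not given in the sources used here. Reads from overlapping or antisense genes cannot be told apart without strand. The reference used for names and lengths belongs to a later mouse build than the authors', so no coordinates are printed.

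Of 30794 transcript lines, 30216 were named through a RefSeq gene table and 180 through GENCODE metadata. The 398 unnamed lines held 1.29% of the RPKM sum in the high and 1.72% in the low library and were left out. The highest of them had 1189 against 4332 RPKM, and the tables used here give no name for it. Further copies of an accession made up 874 lines. A gene's value is that of its transcript line with the highest mean RPKM, a choice made after the layout of the files was seen. Lines at 0 numbered 2815 (9.14%) in the high and 8637 (28.0%) in the low library.

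Depth was recovered from the values. RPKM times transcript length rises in steps of what 1 read is worth, and the best step gave about 115000000 reads for the high and 20900000 for the low library. Among transcripts with 1 to 10 reads, 76.6% of 1638 in the high library and 65.3% of 1061 in the low library lay within 0.1 of a whole read, with lengths from GENCODE that can differ from the authors'. The low library kept 183 transcripts with 1 to 3 reads and 510 with 4 to 10 reads, beside 8287 lines at 0 with a matched length. In the high library these were 574, 681 and 2702. Counting intervals (95%) and the bound of 3 reads for a value of 0 rest on these recovered reads and cover counting error only. Reads expected in the low library are those of the high library divided by the depth ratio and by the scaling of 1.21.

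Changes are log2((high + 1)/(low x 1.21 + 1)), where the factor sets the median log2 ratio of 5167 genes with a mean of 10 RPKM or more to 0. A pseudocount of 1 RPKM understates the change of genes with low values. Genes with a mean of 0.5 RPKM or more were kept, and a change of 2-fold (1 on the log2 scale) was the threshold. A kept gene at 0 in the low library is past this threshold by construction. No test was made, as each group has 1 library. For each of 39 gene lists fixed before the data were examined, the median change and its percentile among 10000 random lists matched on mean expression in 20 bins were computed. Genes named in a list are those with the largest change or those that define it, up to 8 a list. In the immature mTEC list some keratin genes without a change are named as well. Outside the lists, the 15 highest and the 15 lowest changes among genes with a mean of 5 RPKM or more were named, leaving out provisional names, small RNA genes and symbols with more than 1 transcript line. Members of lists that did not match a symbol were not analysed here, and some single genes are not reported here.

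The procedure was tested on simulated data with 15417 genes, 200 of them changed 4-fold, for the comparison of the high with the low library. It called 100% of the genes made 4-fold higher and 71.0% of those made 4-fold lower, and, from counting noise only, 2 unchanged genes (0.0131%), so this share leaves out other errors, such as those behind values of 0 in the low library. Of 100 unchanged lists, 6 lay outside the central 95% of random list medians. Alternatives were other pseudocounts, scalings and filters, fixed beforehand. Others were added after the data were seen: another choice of isoform, single-line genes, genes at 0 left out or at their bound, corrections for GC content, exon length and transcript length, and leaving out fibroblast, endothelial and erythroid list members. Of the kept genes, 98.9% had GC and length values. The rules for the tests of dilution and of erythroid precursors were revised after their results were seen, the former several times with differing outcomes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.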

Results

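Poly(A)-selected RNA was sequenced from medullary thymic epithelial cells (mTEC), the cells of the thymic medulla that display antigens of peripheral tissues to developing T cells. Cells with high and with low surface MHC class II were sorted from pooled thymi of wild-type B6 mice, and each group gave 1 library. The high library was read as pairs of 100 bases and the low library as single reads of 50 bases, so library type and group coincide. The values imply about 115000000 reads for the high library and 20900000 for the low library, a ratio of 5.51. Both listed the same 30794 RefSeq transcript lines, which stand for 23123 gene symbols. The comparison addresses which genes distinguish mature, MHC-II-high mTEC from the MHC-II-low population, which holds immature mTEC among others. With 1 library per group no difference has a replicate check, no test was made, and every statement describes these 2 libraries.

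In the high library, MHC class II and maturation genes and a broad set of tissue-restricted genes stood well above the low library. Aire, the regulator that drives tissue-restricted gene expression in mTEC, was listed at 122 RPKM in the high and 15.9 RPKM in the low library. The insulin gene Ins2 was listed at 21.9 RPKM in the high library and at 0 in the low library. The low library was higher in the chemokine gene Ccl21a, in basal keratin Krt14, and also in collagen, endothelial and adult globin transcripts. Splicing, polyadenylation and chromatin regulators lay close to the midpoint of all genes as groups.

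Of 15590 genes with a mean of 0.5 RPKM or more, 2508 (16.1%) were at least 2-fold higher in the high library and 1457 (9.35%) at least 2-fold lower. Changes are log2 ratios of RPKM plus 1, with the low library multiplied by 1.21 (0.27 on the log2 scale) so that the median ratio of well-expressed genes was 0. With a pseudocount of 5 RPKM in place of 1 the counts were 877 higher and 648 lower. In the main counts, 63.3% of the genes past 2-fold were higher in the high library. That share was 74.9% without scaling and 80.4% with both libraries set to the same upper quartile, so the balance between the directions depends on the scaling. Calls of single genes close to 2-fold depend on it as well. Of the 2508 higher genes, 829 were listed at 0 in the low library, where the filter and the pseudocount together make every kept gene 2-fold higher. Without genes at 0 in the low library the share of higher genes was 53.5%. Of the lower genes, 4 were listed at 0 in the high library. At 1 RPKM or more, 14229 genes were listed in the high and 12808 in the low library. These 829 genes make up most of the 911 at 1 RPKM or more in the high library and below 0.1 RPKM in the low library, against 15 the other way round.

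**Figure D1:**
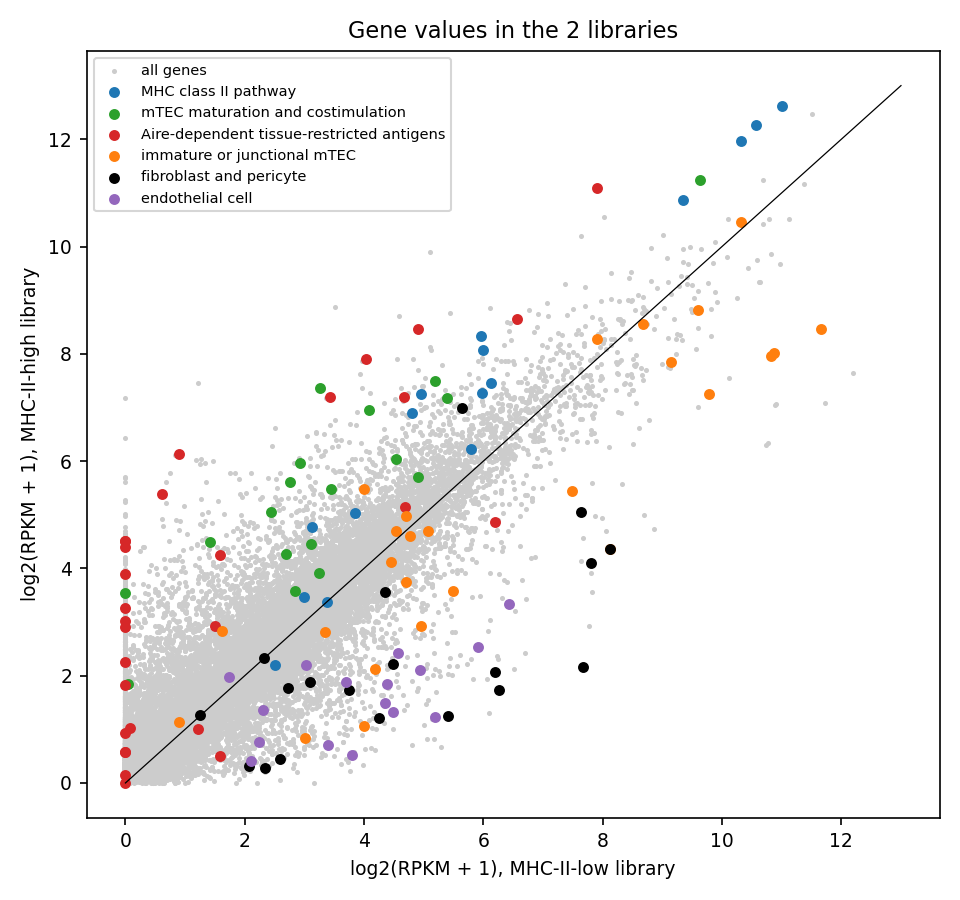
Each point is a gene, placed by its log2(RPKM + 1) in the MHC-II-low library (horizontal) and the MHC-II-high library (vertical), as deposited; colours mark 6 gene lists and the line marks equal values. MHC class II and maturation genes sit above the line, fibroblast and endothelial genes mostly below it, and 9 of the 24 kept Aire-dependent antigens lie on the left edge at 0.

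MHC class II genes, which encode the molecule used for the sort, were higher in the high library. Of 16 measured members, 11 were at least 2-fold higher and 0 were 2-fold lower, with a median log2 change of 1.29 (percentile 100 among 10000 random lists matched on expression). H2-Aa was listed at 4908 RPKM in the high and 1524 RPKM in the low library, a log2 change of 1.41. Cd74, the invariant chain, had 6299 against 2048 RPKM (1.35). The largest change of the list was that of H2-Oa, a modulator of peptide loading, at 2.10. Ciita, the class II transactivator, was higher by 0.92, or by 1.18 without scaling, 1.06 with the same sum and 1.33 with the same upper quartile in both libraries, so its place relative to 2-fold depends on the scaling. MHC class I and immunoproteasome genes had 2 of 15 members 2-fold higher, Psme2 (1.90) and Psmb10 (1.13), and a list median of 0.30 (percentile 90.0), which was 0.57 without scaling and 0.74 with the same upper quartile.

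The maturation and costimulation list had 15 of 18 members at least 2-fold higher and 0 lower, with a median of 1.79 (percentile 100). Aire was higher by 2.61, and the counting interval of its ratio without pseudocount ran from 2.54 to 2.79. Cd80, a costimulatory ligand, had 47.9 against 5.77 RPKM (2.62), and Cd40 had 61.8 against 6.61 RPKM (2.80). Cd86 was listed at 10.6 RPKM in the high library and at 0 in the low library. The chemokine gene Ccl22 had 164 against 8.56 RPKM (3.86) and Hdc, the histidine decarboxylase gene, 180 against 35.5 RPKM (2.04). Fezf2, a second regulator of tissue-restricted genes, was higher by 1.52 and Tnfrsf11a, the receptor RANK, by 1.35. Chemokines as a list had 14 of 23 members higher and 3 lower, a median of 1.36 (percentile 100). The 3 lower ones were Cxcl14 (-3.65), Ccl21a (-3.46) and Cxcl12 (-2.72). TNF receptor and NF-kB signalling genes had 8 of 27 higher and 1 lower (Traf5, -1.24), with a median of 0.48 (percentile 99.8; from 0.27 to 0.86 across all settings). In the same direction, dendritic cell and macrophage markers had 13 of 19 members 2-fold higher and 0 lower, a median of 1.51 (percentile 100; from 0.78 to 2.25 across settings). Among them Lyz2 had 493 against 133 RPKM and C1qb 22.3 against 2.71 RPKM. B cell markers had 7 of 10 higher and 0 lower, a median of 1.10 (percentile 99.7; from 0.47 to 1.51), whereas thymocyte markers had 3 of 20 higher and 0 lower, a median of 0.11 (percentile 39.4; from 0.04 to 0.35). Which cells a transcript came from is not known from these libraries. The shares of mTEC, dendritic cells and B cells in the MHC class II and maturation changes are therefore not known.

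Aire-dependent tissue-restricted antigens had a median of 2.92 (percentile 100), which was 3.56 with genes at 0 set to the bound that a count of 0 allows, 2.26 without the filter and 1.71 with a pseudocount of 5 RPKM. Of 24 kept members among 29, 19 were at least 2-fold higher and 2 lower. The milk protein gene Csn2 had 400 against 93.2 RPKM (1.82), Reg3g 2194 against 237 RPKM (2.93), Tff3 145 against 9.72 RPKM (3.51) and Klk1b16 69.4 against 0.866 RPKM (5.10). Gip and Npy were listed at 21.8 and 20.04 RPKM in the high library and at 0 in the low library. The 2 lower members were Sst (28.1 against 71.8 RPKM, -1.59) and Amy1 (-1.26). A list of antigens reported as independent of Aire or linked to Fezf2 had 11 of 18 members higher and 0 lower, a median of 1.56 (percentile 100), which was 0.66 with a pseudocount of 5 RPKM and 2.34 with 0.1 RPKM. Krt10 had 231 against 14.6 RPKM (3.64) and Ttr, transthyretin, was higher by 2.59, whereas Crp had 10.1 against 11.2 RPKM.

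Genes of single organs that passed the filter were mostly higher in the high library, but in some lists many members did not pass it. The organ lists share members with the Aire-dependent list, among them Reg3g, Tff3, Gip, Npy, Sst and Amy1. Some, such as Ttr, are shared with the list of antigens reported as independent of Aire. They are thus not independent of those 2 lists. Gut and stomach genes had 26 of 27 kept members (28 in the list) 2-fold higher (median 2.65, or 3.29 with zeros at their bound), led by Reg3b with 174 against 1.32 RPKM (6.07). Pancreas genes had 15 of 18 kept members (of 24) higher and 1 lower (median 2.40, 3.57 at the bound and 1.45 without the filter), and Pyy was listed at 50.1 RPKM in the high library and at 0 in the low library. For liver genes the figures were 21 higher and 3 lower of 27 kept among 29 (median 1.53, or 2.09 at the bound), with Apoc3 at 88.4 against 10.2 RPKM and Vtn lower (-2.78). Salivary and lacrimal gland genes had 11 of 14 kept (of 20) higher and 1 lower (median 1.84, 2.27 at the bound and 1.23 without the filter). Thyroid, kidney and lung genes had 9 of 11 kept (of 22) higher and 0 lower (median 1.503, 2.14 at the bound and 0.91 without the filter). Retina genes had 6 of 9 kept (of 22) higher and 0 lower (median 1.98, 3.91 at the bound and 0.58 without the filter), with the lens gene Cryaa at 16.8 RPKM in the high library and 0 in the low library. Testis genes had 5 of 7 kept (of 24) higher and 0 lower (median 1.19, 2.97 at the bound and 0.36 without the filter), and brain genes 10 of 20 kept (of 28) higher and 2 lower (median 0.98, or 0.45 without the filter). With a pseudocount of 5 RPKM these medians lay between 0.40 (brain) and 1.64 (gut and stomach). The percentile of each median among kept genes was 99.46 or more. Among kept members above 0 in the low library, for which the filter does not set the call, 16 of 17 gut and stomach genes were 2-fold higher, 15 of 21 liver, 6 of 9 pancreas, 4 of 7 salivary and lacrimal gland and 6 of 8 thyroid, kidney and lung genes. The figures were 8 of 18 for brain, 1 of 4 for retina, 1 of 3 for testis and 10 of 15 for Aire-dependent antigens. Skeletal muscle and heart genes were mixed, with 11 of 26 kept (of 33) higher and 5 lower. Their median of 0.44 (percentile 97.0) turned to -0.89 among genes with a mean of 5 RPKM or more. Myl1 (-2.89) and Myog, a muscle transcription factor (-1.89), were lower, whereas Tnni1 was higher by 2.74.

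Genes listed at 0 in the low library were unevenly spread. From the reads of the high library and the depth ratio, 102 members of 10 tissue lists had 20 to 200 reads expected in the low library, and 46 of them (45.1%) were listed at 0. The comparison used 8 lists of regulators, housekeeping genes and thymic epithelial identity genes, called regulator lists here. Among 36 of their members with as many expected reads, 0 were listed at 0, which allows a share of up to 8.33%. Weighted to the classes of expected reads that these 36 fall in, the share was 44.4% for tissue list members and 12.9% for all genes. With 5 to 10 expected reads, 2 of 4 regulator members and 6 of 7 tissue list members were at 0. Rps21, a ribosomal protein gene that all cells use, was listed at 144 RPKM in the high library and at 0 in the low library, so a value of 0 may also be a failed estimate.

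**Figure D2:**
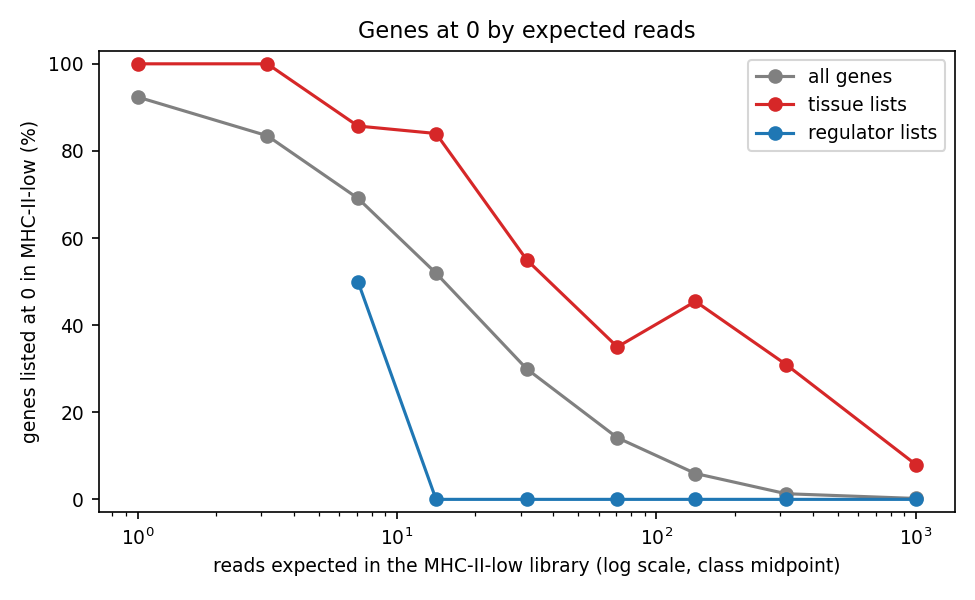
The share of genes listed at 0 in the MHC-II-low library (vertical, percent) is plotted against the number of reads expected there from the MHC-II-high library (horizontal, log scale). Lines are for all genes, members of 10 tissue lists and members of 8 regulator, housekeeping and thymic epithelial identity lists (regulator lists). Classes without genes are not drawn, and the first 2 regulator classes hold 4 and 2 genes. With 20 to 50 expected reads, 30.0% of all genes, 55.0% of tissue list members and 0 of 7 regulator members are at 0.

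Markers of immature or junctional mTEC were lower in the high library, with 14 of 26 members at least 2-fold lower, 2 higher and a median of -1.14 (percentile 0; from -1.22 to -0.71 across settings). Ccl21a, a chemokine that draws thymocytes to the medulla, had 354 against 3238 RPKM (-3.46). Its near-identical copies Ccl21b and Ccl21c share reads with it, so the split between the 3 is uncertain. Apoe had 151 against 876 RPKM (-2.81), Pdpn, podoplanin, 6.62 against 29.8 RPKM (-2.28), and Krt14 231 against 566 RPKM (-1.57). The keratin genes Krt15 (30.5 against 24.9 RPKM, 0.02) and Krt17 (1407 against 1283 RPKM, -0.14) of the same list hardly differed. These libraries do not show which cells a transcript came from, so the share of immature mTEC in this shift is not known. The 2 higher members were Plet1 (1.21) and Tgfb2 (1.04). Moving with this list, fibroblast and pericyte markers had 16 of 19 members 2-fold lower in the high library and a median of -2.37 (percentile 0; from -3.52 to -1.45). Endothelial markers had 15 of 16 lower and a median of -2.86 (percentile 0; from -3.32 to -1.85). Postn, periostin, had 3.48 against 202 RPKM (-5.77), Col3a1 3.18 against 72.5 RPKM (-4.40) and Pecam1 4.79 against 59.2 RPKM (-3.65). Dcn (19.5 against 276 RPKM, -4.03) belongs to both the immature mTEC and the fibroblast list. Rgs5, a pericyte marker, went the other way with 126 against 49.1 RPKM (1.07). Of 5 kept erythroid genes (of 8) 3 were lower and 1, Epb42, was higher (2.25), and the globin gene Hba-a1 had 133 against 1915 RPKM (-4.12). Of 8 kept globin genes 5 were lower and 3, Hba-x, Hbb-y and Hbb-bh1, were higher and at 0 in the low library. The erythroid median of -4.12 was -1.23 among genes with a single transcript line and -0.10 without the filter.

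Thymic epithelial identity genes, such as keratins and transcription factors, showed no common direction, with 3 of 20 members higher, 4 lower and a median of 0.08 (percentile 67.1; 0.52 with the same upper quartile). Epcam had 198 against 127 RPKM (0.37), Foxn1, the master regulator of thymic epithelium, 28.1 against 6.29 RPKM (1.76) and Krt5 448 against 770 RPKM (-1.05, or -0.78 without scaling). Cortical (cTEC) markers had 5 of 17 higher and 2 lower, a median of 0.42 (percentile 96.4; from 0.08 to 0.75). The proteasome subunit gene Psmb11, a cortical marker, had 1.62 against 0.620 RPKM, Ccl25 was higher by 2.68 and Ctsl was lower (-2.26).

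Lists for mTEC subsets that resemble peripheral cell types differed from each other. Keratinocyte or corneocyte-like genes had 16 of 30 members higher and 1 lower, a median of 1.12 (percentile 100; from 0.76 to 1.85), with Krt1 at 62.8 against 1.76 RPKM (4.35) and Spink5 at 44.7 against 7.63 RPKM (2.16). The lower one was Sprr2a1 (-1.78). Microfold-like genes had 6 of 13 higher and 0 lower, a median of 0.91 (percentile 99.6), led by Gp2 with 207 against 28.8 RPKM (2.54). Ciliated and ionocyte-like genes had 7 of 14 higher and 0 lower, a median of 0.86 (percentile 99.2; from 0.40 to 1.31), including the ciliogenesis regulator Foxj1 (1.12). Tuft-like genes had 1 of 25 higher and 4 lower, and their median of -0.46 (percentile 0.375) shrank to -0.05 with the same upper quartile in both libraries. Gng13 had 82.0 against 237 RPKM (-1.79), Il25 29.8 against 60.5 RPKM (-1.27), and Trpm5 33.7 against 45.6 RPKM. Neuroendocrine-like genes had 6 of 18 higher and 2 lower, and their median of -0.21 (percentile 9.08) took the other sign in some settings. Calca was higher by 2.47 and Chgb lower (-2.04).

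**Figure D3:**
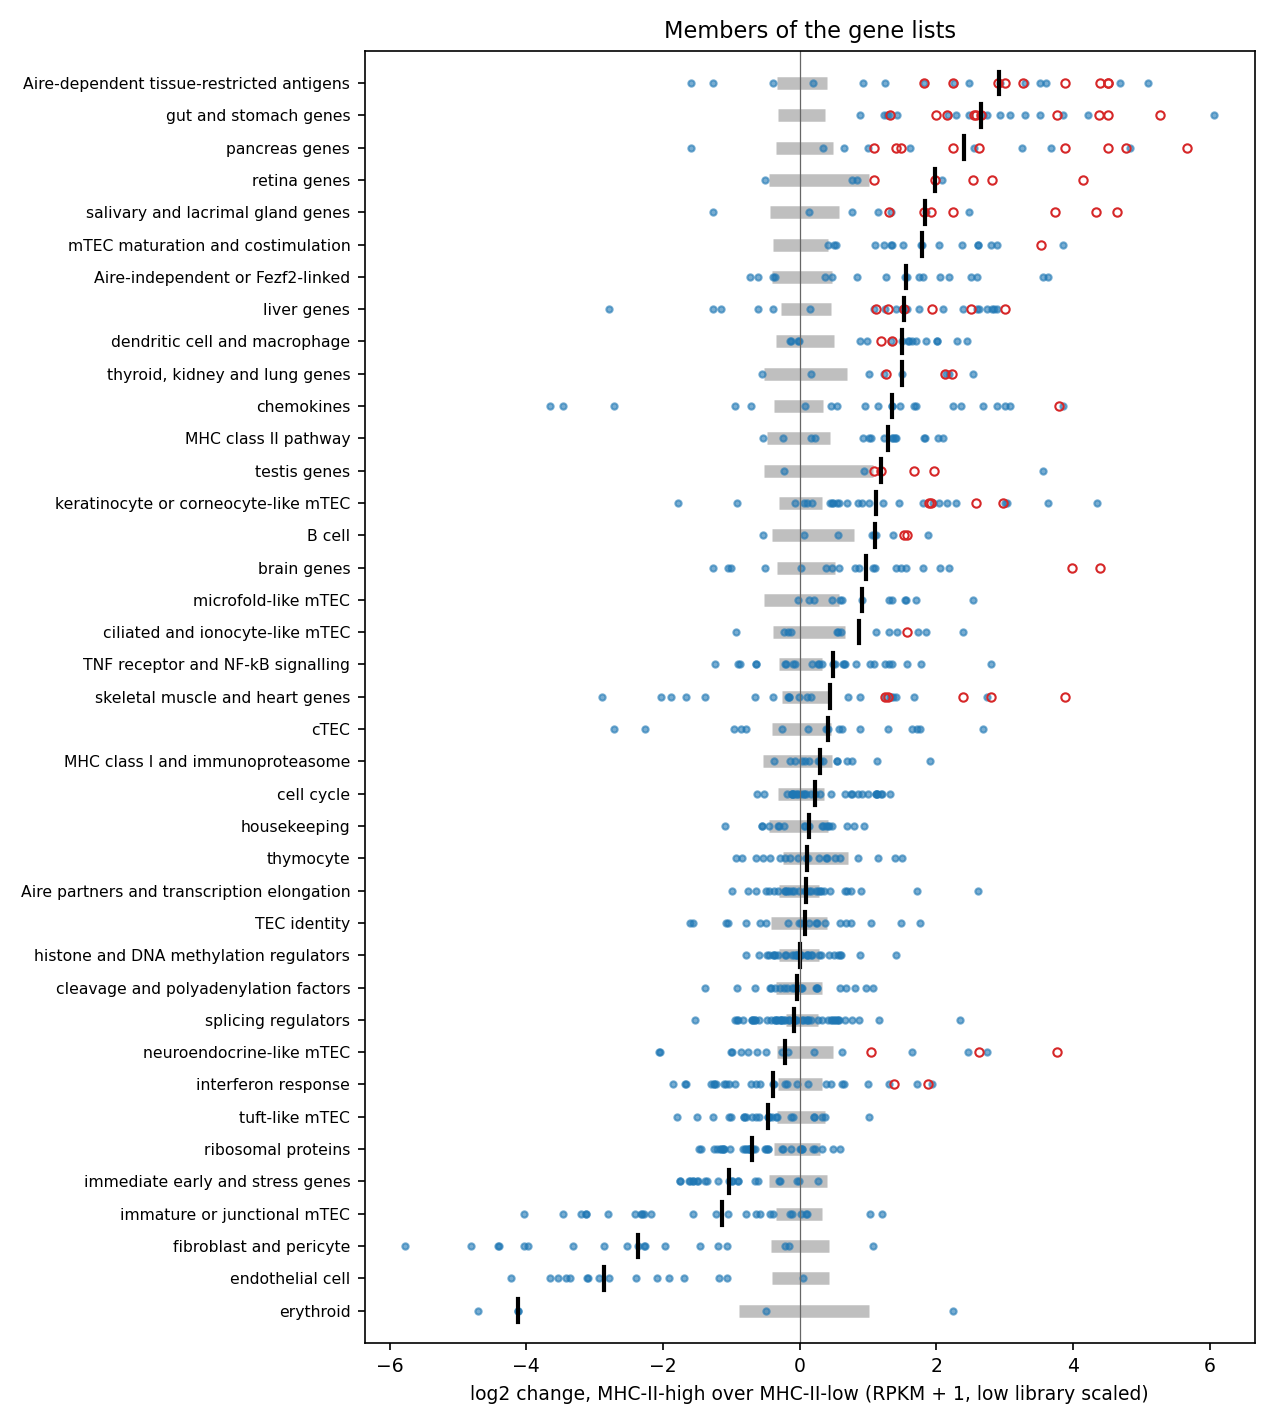
Points are the members of each gene list with a mean of 0.5 RPKM or more, placed by log2 change (MHC-II-high over MHC-II-low, RPKM + 1, low library scaled); open red circles are genes listed at 0 in a library, black bars are list medians, and grey bars span the central 95% of random list medians. Medians are 2.92 for Aire-dependent antigens and -2.86 for endothelial markers; members that did not pass the filter are not drawn.

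Regulators of RNA processing and chromatin, of interest because mTEC use many isoforms of tissue genes, showed few differences of 2-fold or more. Among splicing regulators 2 of 51 were higher, Msi1 (12.3 against 1.33 RPKM, 2.35) and Esrp1 (1.17), and 1 was lower, Rbm24 (-1.53). Their median was -0.09 (percentile 17.6), and 0.30 with the same upper quartile in both libraries. Raver2, a cofactor of the splicing repressor Ptbp1, had 8.89 against 4.33 RPKM (0.67). Cleavage and polyadenylation factors had 1 of 23 higher, Cstf2 (1.07), and 1 lower, Cstf3 (-1.38), with a median of -0.04 (percentile 45.7; 0.35 with the same upper quartile). Clp1, an RNA kinase of the cleavage complex, had 13.4 against 5.26 RPKM (0.97). Clp1 passes 2-fold without scaling and Raver2 with the same upper quartile, so their place relative to 2-fold depends on the scaling. Histone and DNA methylation regulators had 1 of 32 higher, Uhrf1 (1.41), a median of 0.00 (percentile 56.6) and 0.38 with the same upper quartile. Aire partners and elongation factors had 2 of 30 higher, Aire itself and the deacetylase gene Sirt1 (54.6 against 13.1 RPKM, 1.72), and a median of 0.09 (percentile 76.3; 0.42 with the same upper quartile). Cell cycle genes had 8 of 31 higher and 0 lower, a median of 0.23 (percentile 89.0; from 0.15 to 0.59), among them Ube2c (1.32) and Aurka (1.20).

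Control groups did not all stay at the midpoint. Housekeeping genes had 0 of 19 higher and 1 lower, Gapdh with 43.0 against 77.1 RPKM (-1.10), and a median of 0.14 (percentile 76.4). Without scaling these were -0.83 and 0.41, and with the same upper quartile in both libraries -0.67 and 0.57. Ribosomal protein genes had 0 of 36 higher and 10 lower, a median of -0.70 (percentile 0), which was -0.42 without scaling and -0.26 with the same upper quartile in both libraries, with Rps18 at 224 against 508 RPKM (-1.45). Processed pseudogenes are near copies of many of these genes and can share their reads. Immediate early and stress genes had 0 of 23 higher and 12 lower, a median of -1.03 (percentile 0.0100), or -0.76 and -0.59 under these scalings. Jun had 323 against 901 RPKM (-1.75), Fos 527 against 1217 RPKM (-1.48) and the heat shock gene Hspa1b 644 against 1580 RPKM (-1.56).

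Outside the lists, the 15 largest differences toward the high library included Ptgds, a prostaglandin synthase gene, with 68.7 against 0.773 RPKM (5.17). The acute phase gene Saa1 had 467 against 10.4 RPKM (5.11), Psca was higher by 4.92, Muc13, a mucin gene, by 4.67 and Dppa3 by 4.61. The other members of this set, listed at 0 in the low library, were Rps21, Saa2, Klk1b9, Sbpl, Mt4, Rln3, Camp, Hba-x, Prss29 and Sbp. Saa2 had 84.9 and Klk1b9 51.1 RPKM in the high library, and both have close paralogs. Toward the low library, the largest difference was that of Dpt, dermatopontin, with 1.46 against 67.2 RPKM (-5.06). Hbb-bs, a globin gene, had 134 against 3380 RPKM (-4.92), Lars2 200 against 4712 RPKM (-4.83), Ccl11, eotaxin, 25.6 against 462 RPKM (-4.39) and Il6 2.82 against 55.9 RPKM (-4.17). The rest of the 15 were Lrg1, Hbb-bt, Sod3, Aebp1, Sparcl1, Bgn, Selp, Clec3b, Prelp and Sult5a1, with changes between -4.87 and -4.21. The highest transcript line without a name in the tables used here, not part of this ranking, had 1189 against 4332 RPKM.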

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

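The corrections, the other choices of isoform or genes, and the bound for zeros were chosen after the result was seen; the pseudocounts, scalings and filters were planned. The count of genes 2-fold higher was 877 and of lower ones 648 with a pseudocount of 5 RPKM, and 1010 and 822 at a mean of 5 RPKM or more, where fewer genes are tested. With the same upper quartile in both libraries 838 genes were lower, the MHC class II median was 1.73 and the interferon response median turned from -0.38 to 0.0419, since this scaling moves the median of all genes. At 10 RPKM or more, 5488 genes were listed in the high and 4723 in the low library. The Aire-dependent median was 3.64 with a pseudocount of 0.1 RPKM, 1.71 with 5 RPKM and 3.56 with genes at 0 at their bound, as the pseudocount sets the change of genes near 0. Among 2-fold genes 53.5% were higher when genes at 0 in the low library were left out. The log2 factor on the low library was 0.27 in the main setting, 0 without scaling, 0.13 for the same sum and -0.16 for the same upper quartile. The splicing, polyadenylation, methylation regulator, Aire partner and neuroendocrine-like medians lie near 0 and took the other sign in some settings, as did the muscle and heart median; a scaling shifts nearly all genes alike. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. The low library's depth of about 20900000 reads limits the genes with low values.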

Other observations

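The gene families and the tests of explanations were chosen after the result was seen, whereas the interferon list was fixed beforehand. In the high library 22 of 27 kept kallikreins (28 genes), 31 of 35 defensins (73), 31 of 42 keratins (50), 27 of 46 cytochromes P450 (104) and 6 of 7 mucins (8) were at least 2-fold higher, with 0, 0, 2, 3 and 0 lower. A kept gene at 0 in the low library counts as 2-fold higher by construction. Among kept members above 0 there, 16 of 21 kallikreins, 3 of 7 defensins, 19 of 30 keratins, 16 of 35 cytochromes P450, 5 of 6 mucins and 3 of 3 Reg genes were 2-fold higher. Late cornified envelope proteins had 11 of 19 kept members higher and 0 lower, but 1 of 9 above 0 in the low library, and the prolactin family 3 of 6 higher and 1 lower, but 1 of 4. Other families were mixed: serpins had 20 higher and 8 lower of 48 kept, claudins 7 and 4 of 18, Hox genes 4 and 5 of 17 and small proline-rich proteins 11 and 3 of 15. Paralogs in such families share reads, so values of single members are uncertain. Collagens went the other way, with 18 of 33 lower, 3 higher and a median of -1.37. Of 1116 olfactory receptor genes 10 passed the filter, and of 357 vomeronasal receptor genes 0 did.

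Interferon response genes had 6 of 30 members higher and 10 lower in the high library, a median of -0.38 (percentile 0.880) whose sign depends on the scaling, with 0.0419 for the same upper quartile. Of the 8 members with the largest changes, Ifnl2 was listed at 4.37 against 0.329 RPKM (1.94), Ifnl3 at 3.59 against 0.329 RPKM (1.72), and Ifng at 2.68 and Ifnb1 at 1.59 RPKM in the high library and at 0 in the low library. Ifnl2 and Ifnl3 are near copies that share reads. Ifit3 (14.7 against 45.9 RPKM, -1.85), Stat2 (-1.67) and Mx2 (-1.66) were lower, and Oasl1 was higher by 1.32.

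Many tissue-restricted genes were listed at 0 in the low library. Shallower sequencing alone would leave almost none of the tissue list members with 20 to 50 expected reads at 0, but 55.0% of them were. Few molecules read many times in the low library are not the whole cause, because at 20 to 200 expected reads 0 of 36 regulator members were at 0, which allows up to 8.33%, against 45.1% of tissue members or 44.4% at the same read classes, though 2 of 4 regulator members with 5 to 10 expected reads were at 0. An even dilution of mature cells left in the low sort at the share the Aire ratio gives (7.68) stays open. Of 19 Aire-dependent antigens with 10 or more reads expected, 7 were at 0. The rate of all genes gave 3.23 (central 95% from 1 to 6), and the rate of the other tissue lists 7.48. Those lists are part of the pattern itself, so the 2 rates do not decide the question. The 15 members above 0 in both libraries had a median ratio of 9.04. The rule for the count at 0 was revised several times after the result was seen. Its kept form, in which 7 lies above the central 95%, went against even dilution, as did other dropped forms. A dropped form that also asked for an excess over the other tissue lists left dilution open. A difference between the populations and the way the authors counted 50-base reads, with Rps21 at 0, stay open and were not tested.

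Fibroblast, endothelial and adult globin transcripts were higher in the low library, whereas Hba-x, Hbb-y and Hbb-bh1 were at 0 there. A lower share of epithelial cells in the low sort that raises every other type alike stays open. The dendritic cell and macrophage list, with a median of 1.51 in the other direction, cannot decide it. These cells can carry MHC class II, the molecule of the sort. Thymocyte markers were not higher in the low library as a list (median 0.11, from 0.04 to 0.35 across settings). Their median RPKM was low in both libraries (1.02 in the high and 0.965 in the low). Fibroblasts and endothelial cells in the low sort are a candidate source that the counts cannot decide. The 31 of 35 list members 2-fold lower in the high library are the pattern itself. Values in the low library reached 276 RPKM for Dcn and 223 RPKM for Col6a1. Expression of the same genes by MHC-II-low mTEC would give the same count. The pericyte marker Rgs5 was not lower, and sorting for epithelial cells would be meant to remove fibroblasts and endothelial cells. Nucleated erythroid precursors in the low sort stay open, since 0 of the 2 kept erythroid members other than globins were 2-fold lower in the high library, Alas2 (8.73 against 10.47 RPKM) and Epb42, which are too few to decide; an earlier form of this test, with a gene below the filter, excluded them. Expression of these genes by MHC-II-low mTEC themselves, as for Dcn, which 2 lists hold, and globin RNA from red cells were not tested.

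Ribosomal protein and stress transcripts were higher in the low library. A GC content trend between the libraries is not the whole cause, because the medians after its correction were -0.64 and -0.96, against -0.70 and -1.03 before, and -0.42 and -0.76 uncorrected and without scaling. After a correction for an exon length trend between 100 base and 50 base reads they were -0.67 and -0.95. Both pairs stayed below the central 95% of random lists, whose lower ends were -0.37 and -0.44. Those random lists were drawn from uncorrected changes, and none were drawn from corrected ones. Reads shared with pseudogenes, a difference in poly(A) selection, handling during cell isolation and a difference between the populations stay open, since library type coincides with the group.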
